A study of Homo sapiens with 135 samples.

How the data were processed

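Expression of immune genes was measured in 135 samples of formalin-fixed, paraffin-embedded melanoma tissue from 79 patients. RNA was counted on the NanoString nCounter platform, which captures each transcript with a gene-specific probe pair and counts fluorescent barcodes without amplification. Per the labels' protocols, 300 ng of total RNA per sample was run on the PanCancer Immune Profiling Panel. The files used here hold 32 genes of that panel, all 32 of which matched a reference transcript with the same symbol. They hold no housekeeping gene, no positive control and no negative control.

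The authors deposited raw counts per gene for each sample, which are whole numbers from 1 to 73960 with no zero. They also deposited a log2 table of the same genes and samples. In every sample the log2 table equalled the log2 of the raw count plus a constant, to within 1e-08, so the authors had multiplied each sample's counts by a single factor. How that factor was made, and whether background was subtracted, is not given in the sources used here. A factor above 1 raises the counts of a sample. The factor ranged from 0.699 to 101 in baseline samples, from 0.607 to 5.35 in treated samples and from 0.548 to 2.47 in surgery-alone samples. The total over the 32 genes is part of a library and moves with the immune content of the tissue, so it is not the depth of the library.

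Samples were grouped by study arm, visit and injection label. Baseline samples of the treatment arm (n = 39), injected tumours of that arm at weeks 13 to 18 (n = 44) and surgery-alone samples (n = 50) entered the comparisons. The other 2 samples of the treatment arm fell outside these groups and were left out. No label ties a sample to a patient. The 89 untreated samples outnumber the 79 patients, so at least 10 of them are further samples of a patient already sampled, and baseline and treated samples may come from the same patients. Since the 2 arms hold different patients, those further samples lie within the baseline or the surgery-alone group. Every p-value treats samples as independent. Repeated samples of a patient within a group tend to make it too small, pairs across baseline and treated samples could make it too large, and neither effect was measured. No paired fit was possible. Counts of every pair of samples within a group were compared with a chi-square test over genes without HLA-DQA1, and 0 pairs agreed within sampling noise at p above 0.05. The test allows for counting noise only, so it cannot show which samples share a patient or exclude repeated runs.

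The design fixed before the data were examined asked for scaling by housekeeping genes where 3 or more were held and otherwise by the authors' factor, which was used here. Gene tests used edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the deposited counts with the authors' factor as an offset, 1 fit over the 3 groups, no covariate and no filter. P-values were adjusted by the Benjamini-Hochberg method over the 32 genes, with a threshold of 0.05. Standard errors (SE) are the log2 fold change over the square root of F. edgeR's fold changes compare fitted mean counts. Levels are means of log2(scaled count + 1) ± SD.

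The text names, for each contrast, the called genes with the 12 largest rises and the 12 largest falls, plus 14 measured genes fixed beforehand. Results of 2 genes by name are not reported here, and the mean of interferon gamma response genes leaves 1 of them out. Others are named as chosen after their values were seen. Of 22 gene lists fixed beforehand, 8 had 2 or more measured members and were scored. The other 14 had 0 measured members and gave no result: natural killer cell, type I interferon response, regulatory T cell, B cell and plasma cell, macrophage and monocyte, dendritic cell, neutrophil, mast cell, inflammatory cytokine, melanocyte and melanoma, stroma and endothelium, epithelium and keratinocyte, proliferation and apoptosis, and leukocyte total. Lists share members, so their results are not separate from each other. The interferon gamma response list holds all 4 measured chemokine genes. The 18-gene signature holds all 6 measured checkpoint genes and both measured MHC class I genes. A list score is the mean of log2(scaled count + 1) over the measured members. Group means were compared with 2-sided permutation tests of 100000 resamples, whose smallest p is 1e-05, adjusted over 24 list tests. The spread of scores was tested in the same way on the absolute deviation from the group median. List tests, correlations and plots used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

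Tested on simulated counts for the comparison of treated with baseline samples, the edgeR step called 32.9% of genes changed by 1.5-fold, 78.3% of those changed by 2-fold and 1.11% of unchanged genes, over 60 sets of 32 genes. Simulated genes varied independently of each other and changed in random directions, so these rates do not describe genes that move together. The permutation test called 4.5% of unshifted and 98.5% of scores shifted by 1 SD, over 200 sets.

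Alternatives were TMM scaling, total-count scaling, DESeq2 1.42.0 with the authors' factor and with its own size factors, limma 3.58.1 on log2 values, on the deposited table and with sample weights, a mean-count filter of 20, the log2 factor as a covariate, leaving out the 10% of libraries with the highest factor, fitting only the groups compared, robust dispersion, and another reading of the injection labels with 38 baseline and 45 treated samples. List scores were also tested with fry, TMM scaling, a pseudocount of 10, the median of members and the deposited table. The covariate and the left-out libraries were planned on housekeeping counts and used the authors' factor in their place. The median of housekeeping genes was not run, since the files used here hold none.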

Results

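Immune gene expression was profiled in melanoma tissue from a randomised trial of talimogene laherparepvec (T-VEC) followed by surgery against surgery alone. T-VEC is a herpes simplex virus modified to replicate in tumour cells and to express the cytokine GM-CSF, and it is injected into the tumour. In the treatment arm, 39 samples were taken at baseline (week 1) and 44 were injected tumours taken at weeks 13 to 18. The surgery-alone arm gave 50 samples, from weeks 1 to 6. The total raw count over the 32 genes ranged from 356 to 108477 in baseline samples (median 32706), from 13441 to 159655 in treated samples (median 77640) and from 10780 to 179799 in surgery-alone samples (median 47308). The authors' scaling factor also differed between groups. Its log2 was 0.61 ± 1.29 (SD, n = 39) in baseline samples, −0.04 ± 0.54 (n = 44) in treated samples and −0.03 ± 0.45 (n = 50) in surgery-alone samples. Baseline samples thus received a higher factor than treated samples (difference of −0.65 for treated minus baseline, adjusted p = 0.00042) and than surgery-alone samples (0.64, adjusted p = 0.00033; 2-sided permutation tests, adjusted over 6 tests).

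The first comparison asked what changed in tumours between baseline and the end of T-VEC treatment. Of the 32 genes, 26 were higher and 2 were lower in treated than in baseline samples (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). All 5 measured T cell genes rose. CD27, a costimulatory receptor of T cells, was 2.48-fold higher (log2 fold change 1.31 ± 0.33 SE, edgeR adjusted p = 0.000412) and CD3E, a subunit of the T cell receptor complex, was 2.39-fold higher (1.26 ± 0.31). CD3D, another subunit of that complex, was 2.05-fold higher. The T cell list score went from 7.65 ± 1.13 (SD, n = 39) to 8.88 ± 0.84 (n = 44), a difference of 1.24 with a 95% interval from 0.80 to 1.68 (permutation test, adjusted p = 4.8e-05), and 40 of the 44 treated samples lay above the baseline median.

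All 6 measured genes of the CD8 and cytotoxic list were called higher as well, GZMB narrowly. CD8A, the coreceptor of cytotoxic T cells, was 2.39-fold higher (1.26 ± 0.27 SE, edgeR adjusted p = 3.53e-05). Among the granule proteases, GZMK was 2.71-fold higher (1.44 ± 0.28), GZMA 2.14-fold (1.10 ± 0.25) and GZMB 1.503-fold (0.59 ± 0.28, edgeR adjusted p = 0.0469). The cytotoxic granule genes NKG7 and PRF1, which encodes perforin, were 2.02-fold and 1.84-fold higher. The list score rose by 1.22 (95% interval 0.80 to 1.64, permutation test, adjusted p = 4.8e-05), with 41 of 44 treated samples above the baseline median. Adjusted over the list alone, 5 of 5 T cell genes and 6 of 6 CD8 and cytotoxic genes were called higher. IL2RG, the common subunit of several interleukin receptors and a member of no list, was 2.04-fold higher.

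The 4 chemokines measured, which attract T cells and other leukocytes, were all called higher, CXCL10 and CXCL11 narrowly. CCL5 showed the largest increase of the 32 genes, at 2.73-fold (1.45 ± 0.27 SE, edgeR adjusted p = 1.27e-05), from 9.29 ± 1.305 (SD, n = 39) to 11.04 ± 0.84 (n = 44) on the log2(scaled count + 1) scale. CXCL9 was 2.42-fold higher (1.27 ± 0.37) and CXCL10 1.59-fold higher (0.67 ± 0.33, edgeR adjusted p = 0.0484). CXCL11 passed by edgeR (0.68 ± 0.32, adjusted p = 0.0469) and not by limma (adjusted p = 0.186), with 22 of 44 treated samples above the baseline median. The chemokine score rose by 1.16 (95% interval 0.62 to 1.70, permutation test, adjusted p = 0.000216). In the interferon gamma response list, which holds all 4 chemokines, 8 of 11 genes rose, 1 fell and 2 did not pass the test. Adjusted over the list alone, 6 rose and 1 fell. Over all 32 genes 26 rose, so the share of genes that rose was no higher in this list. IDO1, a tryptophan-degrading enzyme, was 2.07-fold higher. The gene that fell was IFNG, which encodes interferon gamma itself, with a log2 fold change of −0.80 ± 0.25 (edgeR adjusted p = 0.00313) and a level of 6.97 ± 1.34 (SD, n = 39) at baseline against 6.42 ± 0.92 (n = 44) after treatment. The list score rose by 0.72 (0.34 to 1.10, permutation test, adjusted p = 0.000351).

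Of 6 immune checkpoint genes, 4 rose, 1 fell and 1 did not pass the test, both over all genes and adjusted over the list alone. The inhibitory receptors LAG3 and TIGIT were 2.21-fold and 1.73-fold higher. CD274, which encodes PD-L1, had a log2 fold change of 0.30 ± 0.19 (edgeR adjusted p = 0.129). CD276, which encodes the surface protein B7-H3 found on many tumour cells, fell, with a log2 fold change of −0.94 ± 0.19 (edgeR adjusted p = 2.93e-05) and 3 of 44 treated samples above the baseline median. The checkpoint score rose by 0.62 (0.31 to 0.93, permutation test, adjusted p = 0.00024). Both measured genes of the MHC class I list rose, also adjusted over the list alone, and its score rose by 0.56 (0.34 to 0.78, adjusted p = 4.8e-05). In the MHC class II list 1 of 3 genes rose, HLA-DRA at 1.62-fold (0.70 ± 0.20), also adjusted over the list alone. Its score differed by 0.26 (−0.52 to 1.04, permutation test, adjusted p = 0.679), but it was higher by 0.76 without HLA-DQA1 (adjusted p = 0.000168) and by fry (adjusted p = 0.00857). This list holds HLA-DQA1, chosen for mention after its values were seen, whose SD within groups was 4.22 to 5.21 on the log2 scale. Of the T cell inflamed 18-gene signature, a published set of T cell, interferon and antigen presentation genes, 17 genes were measured, of which 13 rose and 1 fell, also adjusted over the list alone. The signature includes all 6 checkpoint genes and both MHC class I genes above, so these results overlap. The share that rose was no higher than the 26 of all 32 genes. The signature score rose by 0.78 (0.42 to 1.13, permutation test, adjusted p = 0.00012). The genes that did not pass the test, named because they were few, were CD274, CIITA, CMKLR1 and HLA-DQA1.

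**Figure D1:**
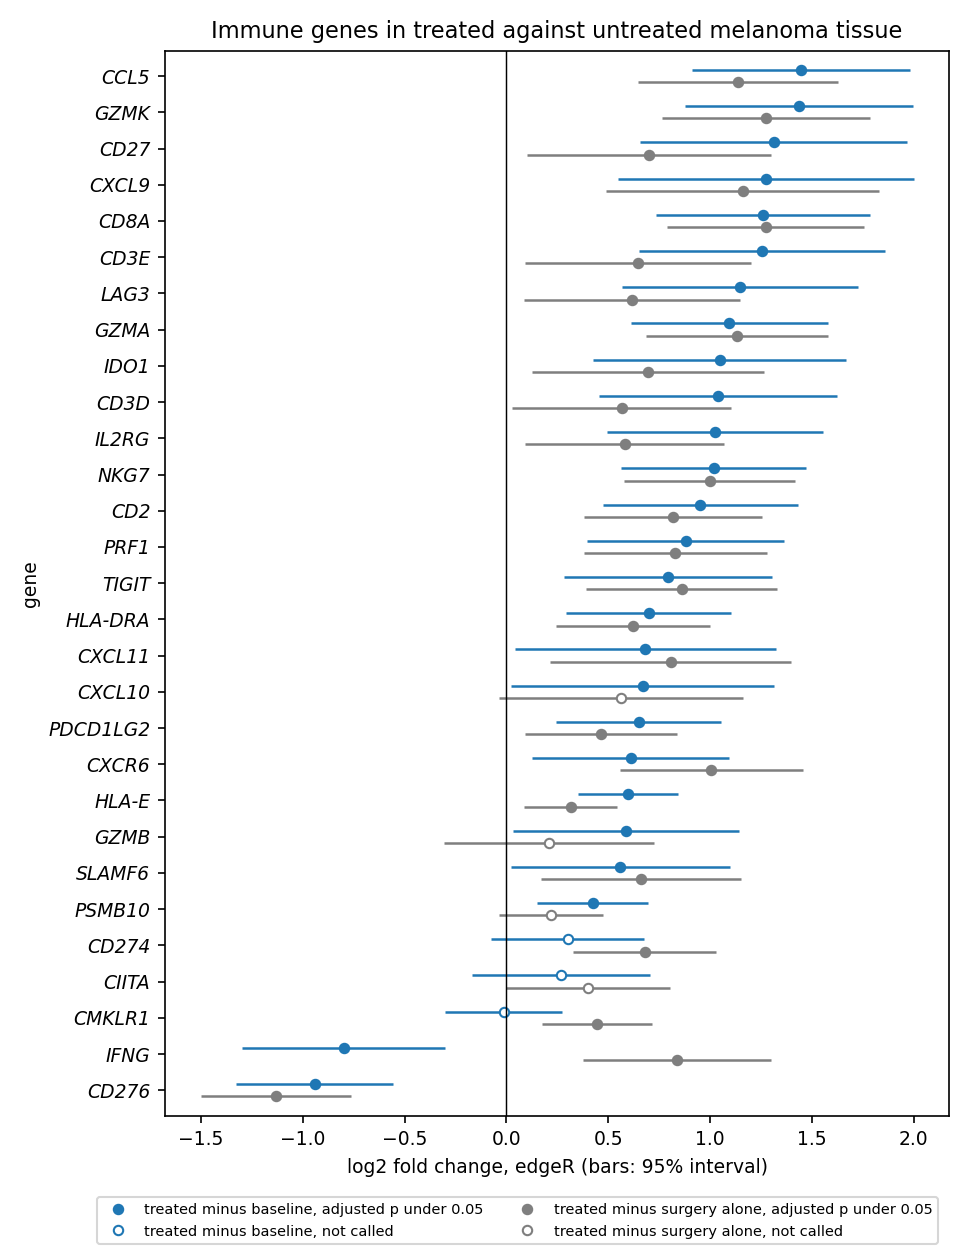
Log2 fold change (horizontal axis, edgeR, authors' scaling) of 29 genes (vertical axis; HLA-DQA1, with 95% intervals over 2 log2 units wide, and 2 others are not drawn) in treated minus baseline samples (blue) and treated minus surgery-alone samples (grey), with bars for the 95% interval and filled points for adjusted p under 0.05. CCL5 (1.45) leads the first contrast and CD276 (−0.94 and −1.13) is the lowest in both; under TMM scaling the fold changes of 11 of the genes drawn turned from positive to negative in the first contrast and 10 in the second.

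These directions are relative to the authors' factor, which left a median log2 fold change of 0.71 over the 32 genes. TMM scaling, which takes a change common to most genes as depth, moved that median to −0.02 and gave 8 higher and 7 lower genes; total-count scaling gave 11 higher and 6 lower. Under TMM scaling 13 fold changes (HLA-DQA1 aside) turned negative, among them CXCR6 of the T cell list, GZMB of the CD8 and cytotoxic list and CXCL10 and CXCL11 of the chemokine list. Higher under all 3 scalings were 8 genes (CCL5, CD27, CD3E, CD8A, GZMA, GZMK, LAG3 and NKG7) and lower under all 3 were CD276 and IFNG. TMM and total-count scaling centre on the 32 genes and lowered their median fold change. Genes already lower under the authors' factor thus stayed lower by construction, so for CD276 and IFNG this is no separate evidence. Under TMM scaling the T cell score was still higher by 0.29 (adjusted p = 0.0182) and the CD8 and cytotoxic score by 0.27 (adjusted p = 0.00101), whereas the interferon gamma response, checkpoint, MHC class I and 18-gene scores were lower, by −0.23, −0.32, −0.39 and −0.17, and the chemokine score no longer passed (0.21, adjusted p = 0.167). CD274 was called lower under TMM scaling (−0.59, edgeR adjusted p = 2.02e-05), total-count scaling (−0.41, adjusted p = 0.00658) and DESeq2's own size factors (−0.58, adjusted p = 3.24e-05). With the authors' factor, limma with sample weights called CD274 higher (0.38, adjusted p = 0.0114). With the log2 factor as a covariate, IFNG (−0.53, edgeR adjusted p = 0.0641), CXCL10 (0.36, adjusted p = 0.328) and GZMB (0.49, adjusted p = 0.115) no longer passed the threshold. Without the 10% of libraries with the highest factor, CXCL10 (0.51, adjusted p = 0.191) and GZMB (0.42, adjusted p = 0.204) did not pass either. The p-values treat samples as independent, although some share a patient.

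**Figure D2:**
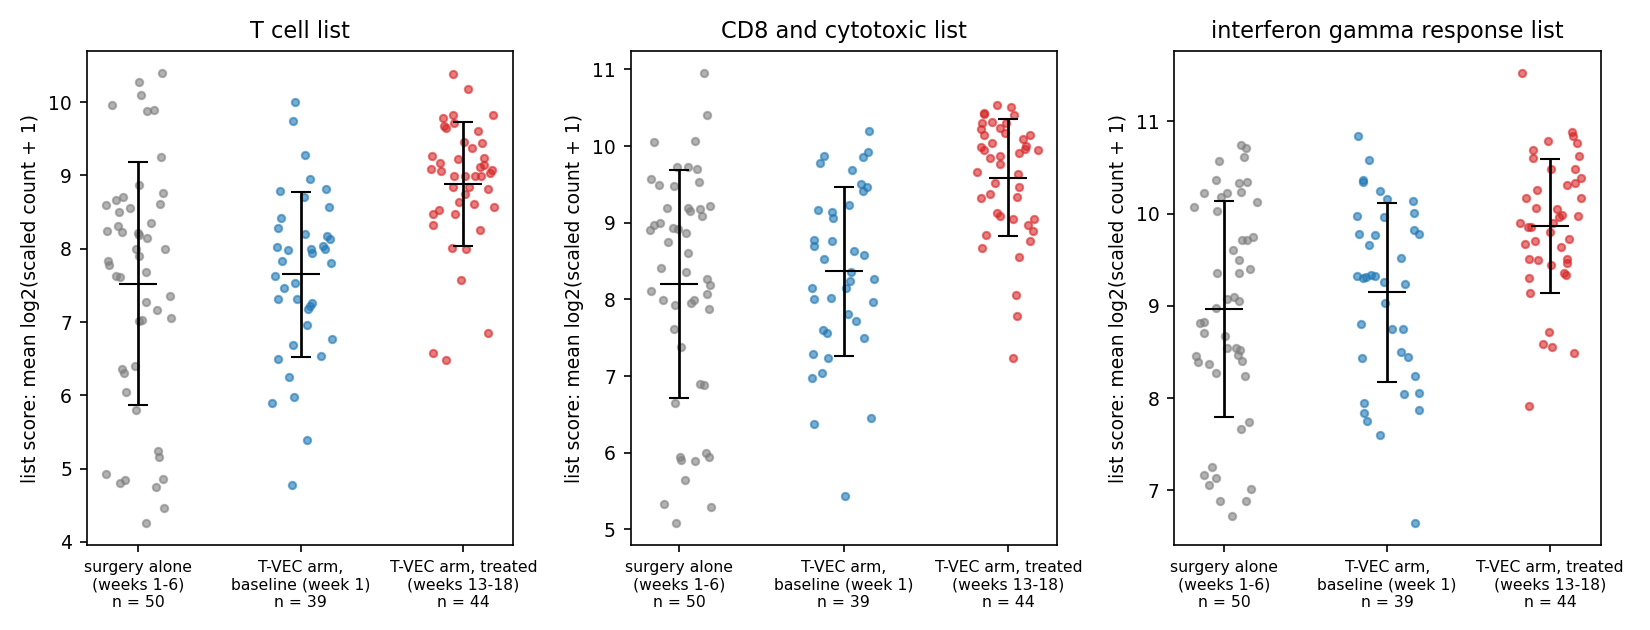
List scores of single samples, as the mean log2(scaled count + 1) of the list's measured genes (vertical axis), for the T cell, the CD8 and cytotoxic and the interferon gamma response lists in surgery-alone (n = 50), baseline (n = 39) and treated (n = 44) samples; black bars are the mean and SD. Treated samples had a mean T cell score of 8.88 against 7.65 at baseline and 7.53 with surgery alone; under TMM scaling the interferon gamma response score of treated samples was lower than at baseline (−0.23).

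The second comparison set treated tumours against tumours of the arm that never received the virus. Here 25 genes were higher and 1 was lower in treated samples. All 5 T cell genes were higher, led by CXCR6, a chemokine receptor of tissue-resident T cells, at 2.01-fold (1.01 ± 0.23 SE, edgeR adjusted p = 7.43e-05), with CD2 at 1.76-fold and CD3E at 1.56-fold. Of the 6 CD8 and cytotoxic genes, 5 were higher. GZMK and CD8A were each 2.42-fold higher (1.27 ± 0.26 and 1.27 ± 0.24), GZMA 2.19-fold and PRF1 1.78-fold, whereas GZMB had a log2 fold change of 0.21 ± 0.26 (edgeR adjusted p = 0.44). The T cell score was higher by 1.36 (95% interval 0.83 to 1.89) and the CD8 and cytotoxic score by 1.38 (0.91 to 1.86; permutation tests, adjusted p = 4.8e-05 for each), with 40 and 41 of 44 treated samples above the surgery-alone median. Adjusted over the list alone, the counts were again 5 and 5.

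Among the chemokines 3 of 4 were higher, CXCL9 by 2.23-fold (1.16 ± 0.34 SE) and CCL5 by 2.20-fold (1.14 ± 0.25), while CXCL10 had a log2 fold change of 0.56 ± 0.30 (edgeR adjusted p = 0.0725). Of 11 interferon gamma response genes 7 were higher and 4 did not pass the test. IFNG, which was lower than at baseline, was 1.79-fold higher than in surgery-alone samples (0.84 ± 0.23, edgeR adjusted p = 0.00119). Of the 6 checkpoint genes 5 were higher, with TIGIT at 1.82-fold, CD274 at 1.60-fold (0.68 ± 0.18) and LAG3 at 1.54-fold, and CD276 was lower (−1.13 ± 0.19, edgeR adjusted p = 3.58e-07). HLA-DRA was 1.54-fold higher, 1 of 2 MHC class I genes was higher, and 13 of 17 genes of the 18-gene signature were higher and 1 lower. The counts for these lists were the same when adjusted over the list alone. The scores of the chemokine, interferon gamma response, checkpoint, MHC class I and 18-gene lists were higher by 1.299, 0.91, 0.65, 0.35 and 0.75 (permutation tests, adjusted p = 0.00018, 0.000187, 0.00032, 0.00403 and 0.00018). The MHC class II score differed by −0.14 (−0.85 to 0.56, adjusted p = 0.754), a result that depends on the setting: it was higher by 0.69 without HLA-DQA1 (adjusted p = 0.00024) and by fry (adjusted p = 0.043), and lower by −1.10 under TMM scaling (adjusted p = 0.00466).

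The median log2 fold change over the 32 genes was 0.67 in this contrast and 0.11 under TMM scaling, which gave 9 higher and 7 lower genes; total-count scaling gave 11 higher and 2 lower. Higher under all 3 scalings were 9 genes, among them CCL5, CD2, CD8A, CXCR6, GZMA, GZMK, NKG7 and TIGIT, and lower under all 3 was CD276. For CD276 this again followed from the centring on the 32 genes and is no separate evidence. DESeq2's own size factors are not among these 3 scalings. With them CD2 (0.09, adjusted p = 0.458) and TIGIT (0.17, adjusted p = 0.189) did not pass. Under TMM scaling the T cell and the CD8 and cytotoxic scores were higher by 0.40 and 0.42, the checkpoint, MHC class I and 18-gene scores turned lower, and the interferon gamma response score (−0.06, adjusted p = 0.496) and the chemokine score (0.34, adjusted p = 0.0537) no longer passed. CD3E did not pass under TMM scaling (0.24, adjusted p = 0.241), under total-count scaling (0.40, adjusted p = 0.103), with DESeq2's own size factors (0.12, adjusted p = 0.589) or without the 10% of libraries with the highest factor (0.54, adjusted p = 0.0743). IFNG did not pass under TMM scaling (0.14, edgeR adjusted p = 0.515) or total-count scaling (0.42, edgeR adjusted p = 0.0827). With DESeq2's own size factors IFNG did not pass either (−0.00263, adjusted p = 0.988), and LAG3 passed under none of these. With DESeq2's own size factors CD274 (−0.27, adjusted p = 0.048) and HLA-DRA (−0.41, adjusted p = 0.0213) were called lower. Differences of mean log2 values were larger than edgeR's fold changes, with a median of 1.08 by limma, which called GZMB (0.84, adjusted p = 0.00302) and CXCL10 (0.91, adjusted p = 0.00477). The p-values treat samples as independent here too.

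Both contrasts use the same treated samples. In the same direction in both, 23 genes were called, of which 22 were higher and 1 lower. Shuffling the group labels over the real samples gave a median of 0 such genes, and independent lists of the same sizes would share 20.4. Shuffled groups mix treated and untreated samples, so they are not groups known to be unchanged. With the treated samples split at random into 2 separate sets, 1 for each contrast, the median was 13 (90% range 10 to 17.1). Each contrast then held only part of the treated samples, so this count was not obtained at the same power as the 23. Over the 32 genes, which are not independent replicates, the fold changes of the contrasts correlated at 0.66 against a median of 0.57 with shuffled labels. The 95th percentile of the shuffled values was 0.804, so the correlation lies within what shuffled labels gave. The covariance was 0.167 against a median of 0.0224 and a 95th percentile of 0.0543 with shuffled labels.

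The third comparison set the arms side by side before any treatment. Of the 32 genes 2 were higher in baseline than in surgery-alone samples by edgeR, and 0 were lower, with 5 genes at an unadjusted p under 0.05. limma on log2 values called 1 gene higher and 0 lower. TMM scaling gave 3 higher and 1 lower, total-count scaling 6 higher and 0 lower and DESeq2's own size factors 3 higher and 8 lower. IFNG was 3.11-fold higher (1.64 ± 0.25 SE, edgeR adjusted p = 1.92e-08), at 6.97 ± 1.34 (SD, n = 39) against 5.42 ± 1.14 (n = 50) on the log2(scaled count + 1) scale, and 35 of 39 baseline samples lay above the surgery-alone median. CMKLR1, the receptor for the chemoattractant chemerin, was 1.37-fold higher (0.46 ± 0.14, edgeR adjusted p = 0.0218). Genes that respond to interferon gamma did not pass the test, with log2 fold changes of −0.11 ± 0.35 for CXCL9 (edgeR adjusted p = 0.881), −0.11 ± 0.31 for CXCL10 and −0.35 ± 0.30 for IDO1. CD8A differed by 0.01 ± 0.25, GZMA by 0.04 ± 0.23, GZMB by −0.38 ± 0.27, PRF1 by −0.05 ± 0.23 and TIGIT by 0.07 ± 0.25. CD3E (−0.61 ± 0.29, edgeR adjusted p = 0.263), CD274 (0.38 ± 0.18, edgeR adjusted p = 0.263), LAG3 (−0.53 ± 0.28) and HLA-DRA (−0.08 ± 0.20) did not pass the test either. Under other scalings some of these passed. CD274 was higher under TMM scaling (0.46, adjusted p = 0.0016), total-count scaling (0.65, adjusted p = 1.15e-05) and DESeq2's own size factors (0.30, adjusted p = 0.0481), LAG3 was lower under TMM scaling (−0.47, adjusted p = 0.0368) and DESeq2's own size factors (−0.58, adjusted p = 0.00268), and CD3E was lower under the latter (−0.42, adjusted p = 0.038).

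None of the 8 list scores passed the test between the arms before treatment (permutation tests, lowest adjusted p = 0.17, for MHC class I, and 0 at an unadjusted p under 0.05). fry, a rotation test of limma, called 0 as well, whereas under TMM scaling the interferon gamma response score was higher at baseline (0.17, adjusted p = 0.0334). The difference was 0.12 for the T cell score (95% interval −0.46 to 0.71), 0.16 for CD8 and cytotoxic, 0.18 for interferon gamma response, 0.03 for checkpoint, −0.21 for MHC class I, −0.40 for MHC class II, 0.14 for chemokine and −0.02 for the 18-gene signature. By edgeR 1 of 11 interferon gamma response genes and 1 of 17 signature genes were called higher and no member of the other lists was called. Adjusted over the list alone the only further call was 1 lower gene of the MHC class I list. CMKLR1 did not pass the threshold with limma (0.44, adjusted p = 0.051), under TMM scaling (0.28, edgeR adjusted p = 0.246), with DESeq2's own size factors (0.083, adjusted p = 0.732) or with only these 2 groups in the fit (0.46, edgeR adjusted p = 0.0628). IFNG passed it in all 15 alternatives run, with log2 fold changes from 1.36 to 2.07. Of these alternatives, the mean-count filter removed no gene and so repeats the main result. The p-values of this comparison also treat samples as independent, although at least 10 untreated samples repeat a patient within a group.

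**Figure D3:**
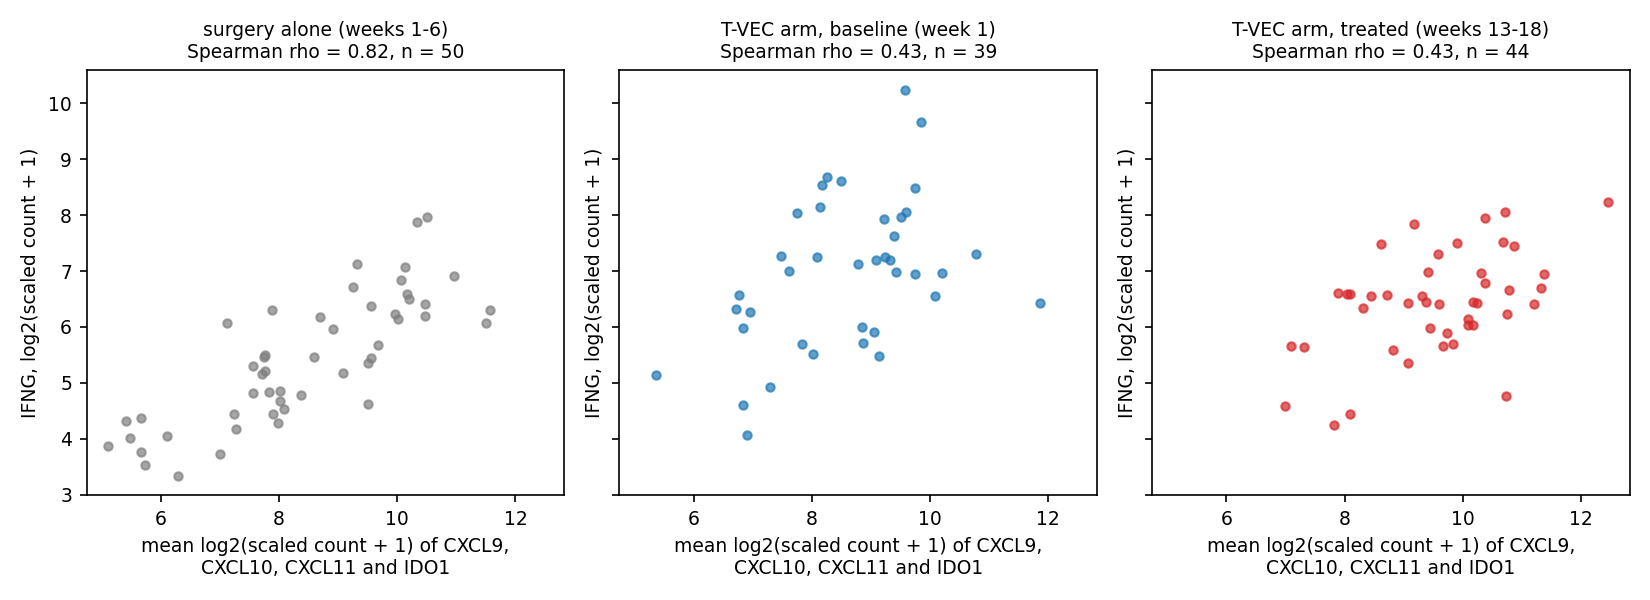
IFNG level (vertical axis) against the mean of 4 interferon gamma response genes (horizontal axis), both as log2(scaled count + 1), with a point per sample in surgery-alone (n = 50), baseline (n = 39) and treated (n = 44) samples. Spearman's rho was 0.82, 0.43 and 0.43 in that order.

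Across samples, IFNG rose with the mean of CXCL9, CXCL10, CXCL11 and IDO1 in each group. In surgery-alone samples Pearson's r was 0.81 and Spearman's rho 0.82 (permutation p = 1e-05 for both, the smallest possible, adjusted p = 3e-05, n = 50). In baseline samples r was 0.44 (permutation p = 0.0059) and rho 0.43 (permutation p = 0.00664, adjusted p = 0.00664, n = 39), and in treated samples r was 0.49 (permutation p = 0.00067) and rho 0.43 (permutation p = 0.00444, adjusted p = 0.00533, n = 44). Without the 2 samples farthest from the median of the response genes, r was 0.83, 0.47 and 0.37 in the same order. These relations, chosen after the values were seen, belong to a family of 6.

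The last comparison asked whether treated tumours varied more than baseline tumours. The SD of the T cell score was 0.84 in treated samples (n = 44) and 1.13 at baseline (n = 39), that of the CD8 and cytotoxic score 0.76 and 1.10, and that of the 18-gene score 0.66 and 0.91. The mean absolute deviation from the group median was lower in treated samples for 7 of the 8 lists, by −0.28 for T cell, −0.30 for CD8 and cytotoxic, −0.23 for interferon gamma response, −0.19 for checkpoint, −0.16 for MHC class I, −0.21 for chemokine and −0.31 for the 18-gene signature, and it was higher by 0.17 for MHC class II. No list passed the adjusted threshold (permutation tests, adjusted p from 0.0697 to 0.368), and 3 had an unadjusted p under 0.05. Under TMM scaling the sign turned in 6 of these 7 lists, with no adjusted p under 0.422.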

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

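The choice of scaling moved the results most. TMM, total-count scaling and DESeq2's own size factors take their scale from the 32 immune genes, so by construction they remove a change common to them. They gave 15, 17 and 18 genes changed after treatment (main value 28), 16, 13 and 15 genes between treated and surgery-alone samples (26), and 4, 6 and 11 genes between the arms before treatment (2). Of DESeq2's 18, 15 and 11 genes, 11, 6 and 3 were higher. Under TMM scaling 13 log2 fold changes, HLA-DQA1 aside, turned from positive to negative for treated minus baseline, among them CD274 −0.59, CXCL10 −0.068, GZMB −0.13 and HLA-DRA −0.011. Among those that turned were CD274 −0.41 with total counts, and with DESeq2's size factors CD274 −0.58, CXCL10 −0.052, GZMB −0.095 and HLA-DRA −0.047. Of the genes given here only CD274 passed as lower, under all 3. For treated minus surgery alone 11, HLA-DQA1 aside, turned under TMM scaling, among them CD274 −0.13, HLA-DRA −0.20 and IDO1 −0.049, and with DESeq2's size factors CD274 −0.27, HLA-DRA −0.41, IDO1 −0.11, IFNG −0.00263 and LAG3 −0.00337, of which CD274 and HLA-DRA passed as lower. Called higher by the main test and lower under TMM scaling were 2 genes in the first contrast and 3 in the second. Under TMM scaling the scores of treated minus baseline samples turned to −0.23 for interferon gamma response, −0.32 for checkpoint, −0.39 for MHC class I and −0.17 for the 18-gene signature, and chemokine no longer passed (0.21). Against surgery alone they turned to −0.056 (not past the threshold), −0.31, −0.62 and −0.21, chemokine no longer passed (0.34) and MHC class II now did (−1.10). Baseline minus surgery alone passed for interferon gamma response (0.17).

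With the authors' scaling kept, the count between the arms was 1 with limma on log2 values, 1 on the deposited table and 1 with only the groups compared in the fit. It was 4 with counts under 20 set to 20, a setting added after seeing the data; the cause was not tested. The counts of the first 2 comparisons stayed within 1.5 times under these alternatives (22 to 29 and 23 to 31 genes); leaving out the 2 libraries under 5000 counts, also added, gave 28, 27 and 2. The mean-count filter removed no gene and says nothing about stability. Of the named genes' values under these alternatives, that filter's unchanged values included, 591 kept their direction and their side of the threshold. Another 24 that were not past it changed sign, 11 no longer passed and 10 newly passed. Those that no longer passed were 4 values of CXCL10, 2 of GZMB and 1 of IFNG against baseline, 1 of CD3E against surgery alone and 3 of CMKLR1 between the arms. CXCL10 did not pass without libraries under 5000 counts (0.64, adjusted p = 0.0606) or with counts under 20 set to 20 (0.67, adjusted p = 0.0596). With HLA-DQA1 left out, an added setting, the MHC class II score rose against baseline (0.76) and surgery alone (0.69), where it had been −0.14. fry, which weighs each member by its own spread, called it higher in both (adjusted p = 0.00857 and 0.043). Leaving that gene out also turned the difference in spread of the MHC class II score (−0.34) and let that of the 18-gene signature pass (−0.26). Against surgery-alone samples, an added reference, treated samples deviated less for T cell (−0.72), CD8 and cytotoxic (−0.59), interferon gamma response (−0.42), checkpoint (−0.29), MHC class I (−0.22), chemokine (−0.49) and the 18-gene signature (−0.41), and more for MHC class II (0.33). Under TMM scaling, also added, none of these passed (lowest adjusted p = 0.27), with −0.13 for T cell and −0.085 for CD8 and cytotoxic. No housekeeping gene was held, so the planned median of housekeeping genes was not run, and the 2 planned housekeeping alternatives used the authors' factor. No paired analysis was possible because the labels name no patient. Depth limits the genes with the lowest levels most, which in surgery-alone samples were IFNG, SLAMF6 and CD274 (5.42, 5.81 and 6.01 on the log2 scale).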

Other observations

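Ratios of 2 genes within a sample are free of any scaling factor. They are not free of background counts, whose handling is not known and which weigh most on the low genes IFNG and CD274. The 6 ratios below were chosen after the gene results were seen and tested in a family of 18 (6 ratios in 3 contrasts, 2-sided permutation tests with Benjamini-Hochberg adjustment). The ratio of CD8A to CD276 was 5.47-fold higher in treated than in baseline samples (log2 difference 2.45, 95% interval 1.76 to 3.15, adjusted p = 3.6e-05, 42 of 44 treated samples above the baseline median) and 6.41-fold higher than in surgery-alone samples (adjusted p = 3.6e-05). The ratio of CD274 to CD8A was lower in treated samples, with a log2 difference of −1.16 against baseline (adjusted p = 3.6e-05) and −0.90 against surgery alone (adjusted p = 9e-05). CD274 encodes PD-L1 and CD8A the coreceptor of cytotoxic T cells. GZMK is most often found in memory-like and GZMB in effector cytotoxic lymphocytes. The ratio of GZMK to GZMB was 1.67-fold higher in treated than in baseline samples (log2 0.74, 95% interval 0.30 to 1.18, adjusted p = 0.00228, 36 of 44 above the baseline median) and 1.82-fold higher than in surgery-alone samples (0.86, 0.39 to 1.33, adjusted p = 0.0009).

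Of the chemokines, the ratio of CXCL9 to CXCL10 was 1.97-fold higher than at baseline (adjusted p = 0.00036) and 1.53-fold higher than with surgery alone (adjusted p = 0.0127). The ratio of IFNG to CXCL9 had a log2 difference of −2.27 against baseline (adjusted p = 3.6e-05) and −0.50 against surgery alone (adjusted p = 0.0862). The ratio of CD8A to CD3E differed by −0.01 from baseline (adjusted p = 0.934) and was 1.31-fold higher than with surgery alone (adjusted p = 0.0201). Before treatment, the arms differed in IFNG to CXCL9 (1.77, adjusted p = 3.6e-05) and CD8A to CD3E (0.41, adjusted p = 0.0325). Among libraries with a factor of 0.8 to 1.3 (28 treated, 23 baseline and 24 surgery-alone), the ratios of CD8A to CD276 and of CD274 to CD8A kept their direction and passed against both groups (adjusted p from 0.00018 to 0.0494). The GZMK to GZMB ratio differed by 0.66 and 0.72 with adjusted p = 0.0758 and 0.11, and CXCL9 to CXCL10 by 0.28 and 0.42 with adjusted p = 0.492 and 0.345. The ratio of IFNG to CXCL9 differed by −0.97 from baseline in these libraries (adjusted p = 0.0758). Between the arms before treatment, neither ratio passed there: IFNG to CXCL9 differed by 0.31 (adjusted p = 0.607) and CD8A to CD3E by 0.28 (adjusted p = 0.429). A subset by total count, 30000 or more, was tried first and replaced because the total over these genes moves with immune content. In it the GZMK to GZMB ratio differed by 0.72 and 0.72 (adjusted p = 0.0395 and 0.0233). Between the arms before treatment, IFNG to CXCL9 differed by 0.88 in that subset (adjusted p = 0.0475) and CD8A to CD3E by 0.42 (adjusted p = 0.0934).

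In the weighing below, the tests of IFNG in libraries of similar factor, of the mean of 4 response genes in all and in those libraries, of the correlation of IFNG, of IFNG and CD276 in raw counts and of spread in libraries of similar factor were chosen after the results were seen. The last of these replaced a test planned on libraries with a total of 30000 or more, for the same reason, which gave a difference in deviation of −0.45 for the T cell score (permutation p = 0.00751, adjusted p = 0.0339) and −0.33 for CD8 and cytotoxic (permutation p = 0.0314, adjusted p = 0.0628). The bound for calling the upper distance of the T cell score shortened was also set after its value was seen. Of 100 splits of the samples, the real one included, 1 gave 28 or more genes for treated against baseline samples, and the highest other split gave 7. For treated against surgery-alone samples 1 of 100 splits gave 26 or more, and the highest other gave 12, so chance is argued against for both counts, with splits that treat samples as independent. For the arms before treatment 9 of 100 splits gave 2 or more genes, and the highest other gave 20, so chance is not excluded for that count.

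IFNG was higher in baseline than in surgery-alone samples by 1.55 on the mean log2 scale (95% interval 1.01 to 2.08), although the arms were assigned at random and neither had received the virus. Scaled-up background in shallow libraries is argued against as the whole cause, since the difference stayed at 1.15 (0.49 to 1.80) in the 23 baseline and 24 surgery-alone libraries with a factor of 0.8 to 1.3. Higher interferon gamma signalling stays open. The mean of CXCL9, CXCL10, CXCL11 and IDO1 differed by 0.139 (−0.495 to 0.773), an interval that overlaps that of 0.5 times the IFNG difference (0.505 to 1.04), and in libraries of similar factor it differed by 0.651 (−0.23 to 1.54), too wide to decide. Another candidate explanation that stays open is that part of the IFNG counts at baseline did not come from the transcript that drives these genes, as rho with them was lower than in surgery-alone samples by −0.388 (permutation p = 0.001), and 0.45 against 0.83 in libraries of similar factor. Treated samples had a rho of 0.43, as low as at baseline, so the weaker relation is not particular to the baseline group. The comparison of rho did not account for spread within groups. The SD of the chemokine score was 1.34 at baseline and 1.67 with surgery alone, while that of IFNG was 1.34 and 1.14. The labels do not say whether biopsies and resected tissue were divided between the groups, so a difference in how tissue was taken was not tested.

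CD276 was lower in treated tumours than in both untreated groups. Against surgery alone, the authors' scaling is argued against as the whole cause, since raw counts without it differed by −0.90 on the log2 scale (95% interval −1.38 to −0.43) in all libraries and by −1.01 (−1.66 to −0.36) in those with a factor of 0.8 to 1.3. Against baseline the scaling and a lower CD276 level cannot be told apart, because raw counts differed by −0.718 (−1.11 to −0.32) in libraries of similar factor but by −0.29 (−0.86 to 0.28) in all, where the factor differs between the groups. Within untreated samples CD276 fell as the T cell score rose, with Spearman's rho of −0.61 at baseline (n = 39, permutation p = 3e-05, adjusted p = 6e-05; Pearson's r −0.61 with permutation p = 3e-05, and −0.60 without the 2 farthest samples) and −0.71 with surgery alone (n = 50, permutation p = 1e-05, the smallest possible, adjusted p = 3e-05; r −0.77 with permutation p = 1e-05, and −0.74). The slope of −0.52 (95% interval −0.62 to −0.41) times the rise of the T cell score by 1.24 predicts 67.5% of the fall against baseline (54.0% to 81.0% from the slope's error alone). The slope and both changes were taken under the authors' factor. Under that factor the fall may thus be largely a dilution of tumour-cell RNA by leukocyte RNA, a hypothesis that no melanocyte gene in these files can check, and a loss of tumour cells or of CD276 per cell stays open. The share depends on the scaling: TMM, which removes what the 32 genes share, gave a T cell score rise of 0.29 and a CD276 log2 fold change of −2.04.

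Scores of T cell and cytotoxic genes were less spread in treated than in surgery-alone tumours, with a T cell SD of 0.84 (n = 44) against 1.66 (n = 50). High-factor libraries are argued against as the cause, because the difference in mean absolute deviation of the T cell score was −0.841 in the 28 treated and 24 surgery-alone libraries with a factor of 0.8 to 1.3 (permutation p = 0.00147) against −0.72 in all, and that of CD8 and cytotoxic was −0.58 (permutation p = 0.00359) against −0.59. The log2 factor itself differed by −0.01 between these groups (permutation test, adjusted p = 0.904). Shallow libraries stay open as part of the cause, because that range of factors does not leave them out. With a total of 30000 or more, a subset that moves with immune content, the differences were −0.45 and −0.33 (permutation tests, adjusted p = 0.0339 and 0.0628). In all libraries under TMM scaling, which removes what the 32 genes share, the differences were −0.13 (adjusted p = 0.364) and −0.085 (adjusted p = 0.364) and did not pass. A candidate biological explanation is that tumours poor in T cells were missing from the treated group. The distance from the 10th percentile to the median was shorter by −1.999 (95% bootstrap interval −2.61 to −0.34), but that from the median to the 90th percentile was also shorter by −1.27 (−1.81 to 0.02), so a missing low end and a general narrowing cannot be told apart. Whether treated tumours that shrank away left no tissue to sample was not tested.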
